A study of Homo sapiens with 6 samples.

How the data were processed

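RNA was extracted with Trizol from frozen left ventricular tissue of ARVC patients and made into libraries with an Illumina TruSeq RNA kit from total RNA, per the labels' protocols. The submitters' processing notes name the genome build hg19 and the tools TopHat2 2.1.1, Cufflinks 2.2.1 and DESeq2, with no roles; the counting tool, the gene annotation, the use of strand and the set of libraries behind the normalisation are not given in the sources used here. The deposited values are a signal: read counts per gene divided by 1 DESeq2 size factor per library by the authors, with 25369 gene symbols and 1 column per heart. There was 1 column for each sample and 0 other columns of values.

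In each column all values were whole multiples of 1 step, so whole reads were recovered by dividing by that step: 100% of values came out whole within 0.01 of a read. The recovered totals were 35911701 to 70300115 reads. The deposited size factors were 0.746 ± 0.00389 times (SD, n = 6; range 0.740 to 0.751) those computed from these 6 columns alone, so their overall scale was not set by these 6 columns alone. The ratio was nearly the same in every heart and does not affect comparisons between hearts. A count test between groups could not be run with 1 group. The recovered reads were used for RPM, TMM factors and dispersion in edgeR 4.0.16 (R 4.3.3). The edgeR common biological coefficient of variation was 0.336 with 6 hearts and 0.278 without heart 6, over 17543 genes.

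The labels number the 6 samples and do not say whether each came from a different person, so p-values measure the spread between these samples. Values were transformed as log2(value + 1), which understates changes of low genes. A gene was called detected at a mean normalised count of at least 10. Each list score is the mean over detected members of the log2 value minus the gene's mean. The tests, gene lists, gene pairs and alternatives were fixed before the data were examined. Ratios inside a heart were tested with an exact two-sided sign-flip test over 64 sign patterns, and correlations between list scores with exact permutation of pairings (720 orders), each with Benjamini-Hochberg adjustment. With 18 ratio pairs and a smallest p of 0.03125, at least 12 pairs must reach it for any to pass, so each pair's call depends on the others. Spread and coherence of a list were placed among 10000 random lists matched on mean expression in 50 bins; this describes these libraries and is not a test, and chance alone places about 2% of lists at or above the 98th percentile. Lists needed at least 4 detected members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.

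The text names the 15 most abundant genes; for each list the 2 highest and the 2 most variable members, and all 5 desmosome genes; the genes of the fixed pairs; the 20 genes with the largest and the 10 with the smallest SD for their level among genes with a mean of at least 50; and the 10 highest listed long noncoding RNAs. Not all of them are printed. Genes whose level can reveal something carried by one person, 163 in all, were left out of every result on single genes, lists and ratios. They were Y-linked, X-inactivation, HLA, immunoglobulin and T cell receptor genes and common germline deletions. They were kept in values of whole libraries: read totals, genes with a read, size and TMM factors, edgeR dispersion and the comparison of read counts between libraries. A further 28 symbols had been turned into dates by a spreadsheet and held 0.147% of reads; they were left out of gene results. Genes encoded by mitochondrial DNA were not analysed here. The gene annotation used for exon lengths, GC content and overlap of genes was GENCODE 29 on GRCh38, which matched 22551 symbols (88.9%), and RefSeq on GRCh38.p14 gave gene classes; since the authors used hg19, no coordinates are given.

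The alternatives were pseudocounts of 0.5 and 5, CPM, TMM, no minimum and a minimum of 50, each heart left out in turn, Spearman correlation, a median score, ratios per kilobase and, added after seeing the data, leaving out genes that overlap a detected gene on the other strand. Upper quartile scaling was not run, since TMM served for that alternative.

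The steps were tested on simulated data drawn from the real means and library sizes. Of 200 genes changed 4-fold in 3 of 6 hearts, 84.5% were among the 200 most variable of 14876 genes, and of those changed 2-fold 22.5%. Over 17738 genes, 76% of lists of 15 genes sharing a change with an SD of 0.5 on the log2 scale were called more variable and 98% coherent, against 4% and 1.5% of unchanged lists. When 14 of 18 pairs had a true ratio of 4, 99% of them passed, and 14.4% at a true ratio of 2, in a simulation on 36 genes. The number 14 equals the number of pairs that passed in the real data. When each pair had a true ratio of 1 or 2 at random, 0% of those with a ratio of 2 passed. The spread of the simulated genes was a fixed setting, so these shares may be too high for pairs that varied more. Unrelated list pairs had an unadjusted p of 0.05 or less in 3.57% of simulated tests. Genes varied independently in that simulation, so the rate does not cover lists that correlate through variation shared by many genes.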

Results

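Gene expression was measured by RNA sequencing of left ventricular tissue from patients with arrhythmogenic right ventricular cardiomyopathy (ARVC), an inherited disease in which heart muscle is replaced by fibrous and fatty tissue and which is often caused by variants in genes of the desmosome, the junction that holds heart muscle cells together. The labels gave 6 samples in 1 group, called hearts 1 to 6 here after their replicate numbers. No control tissue was analysed here, so levels, spread between hearts, ratios of gene pairs inside each heart and relations between gene lists were described, and no gene could be called higher or lower in disease. The number of reads assigned to genes ranged from 35911701 to 70300115 per heart. Of 25369 gene symbols, 17738 had a mean normalised count of at least 10 and were called detected. Levels below are in RPM, the reads of a gene divided by all reads assigned to genes and scaled to the same total in each heart, as mean ± SD (n = 6 hearts), and fold ranges between hearts are of normalised counts. Intervals and floors cover counting error only, and a count of 0 allowed a level of up to 0.0427 to 0.0835 RPM, depending on the heart.

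The 15 most abundant genes, ranked by reads with no correction for transcript length, included genes of the contractile apparatus and noncoding RNAs. TTN, which encodes the giant spring protein titin, took 8.78 ± 2.91% of all reads, with a range of 5.34 to 13.99% between hearts, or to 9.002% without heart 3. MYH7, the slow cardiac myosin heavy chain, reached 27368 ± 5972 RPM, and the intermediate filament gene DES reached 9990 ± 1722 RPM (10576 ± 1064 RPM without heart 3). MB (myoglobin), ANKRD1 (a stretch-responsive gene), RYR2 (the calcium release channel), TPM1, MYL2, AHNAK, CMYA5 and ACTC1 were also among the 15 most abundant genes, at means of 3782 to 6321 RPM. Noncoding RNAs of that set were RPPH1, the RNA of ribonuclease P, at 15184 ± 2182 RPM, RMRP, the RNA of ribonuclease MRP, at 14209 ± 5564 RPM, and MALAT1 at 6069 ± 2271 RPM. PLCG2, a phospholipase gene, stood at 4612 ± 2031 RPM.

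The 5 desmosome genes were all detected. DSP and PKP2 had more reads than JUP, DSG2 and DSC2 in every heart. The read ratio of DSG2 over DSC2 did not pass the test described below, and JUP and DSG2 were not tested against each other. These levels rank reads with no correction for transcript length, so the order need not be that of transcript numbers. DSP (desmoplakin) was the highest at 769 ± 66.7 RPM (795 ± 21.8 RPM without heart 4) and PKP2 (plakophilin 2) followed at 458 ± 90.2 RPM. JUP (plakoglobin) stood at 92.8 ± 29.7 RPM (81.2 ± 10.4 RPM without heart 6), DSG2 (desmoglein 2) at 75.8 ± 9.31 RPM and DSC2 (desmocollin 2) at 63.7 ± 8.81 RPM. The desmosome list did not vary more between hearts than other genes of like expression: its median SD of 0.25 on the log2 scale lay at the 39.3rd percentile of 10000 random lists. Among the other junction genes, CTNNB1 (beta-catenin) had an SD of only 0.06 on the log2 scale, whereas the gap junction gene GJA1 (connexin 43) ranged from 229 to 794 RPM (from 384 RPM without heart 6 and to 479 RPM without heart 2). The list of other ARVC-associated genes (45.9th percentile) included DES, PLN at 2631 ± 875 RPM and TGFB3 at 38.0 ± 16.7 RPM (32.3 ± 10.3 RPM without heart 4).

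**Figure D1:**
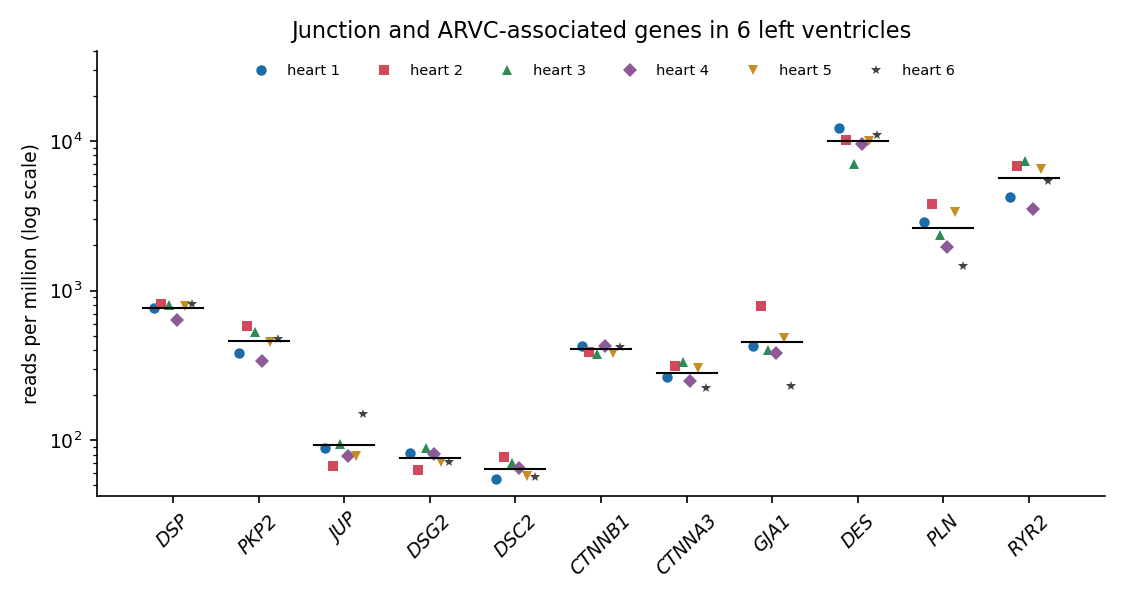
Levels of 11 cell junction and ARVC-associated genes in RPM (log scale) in 6 left ventricles; each symbol is 1 heart and each bar the mean. The levels of DSP and PKP2 averaged 769 and 458 RPM, above JUP, DSG2 and DSC2 in every heart, with no correction for transcript length.

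Within each heart, 18 gene pairs fixed before the data were examined were compared, which asks which of 2 related genes had more reads. Genes typical of adult ventricular muscle had more reads than their atrial or fetal counterparts. MYH7 exceeded MYH6, its fast counterpart, by 6.68 ± 1.28 on the log2 scale, and the ventricular light chain genes MYL2 and MYL3 exceeded the atrial MYL7 and MYL4 by 3.501 ± 1.32 and 4.81 ± 1.89. The adult troponin gene TNNI3 exceeded the fetal TNNI1 by 7.62 ± 0.75, and PLN exceeded the atrial SLN by 9.84 ± 1.35. Among junction and channel genes, GJA1 exceeded GJA5 by 4.54 ± 1.20 and CTNNA1 exceeded CTNNA3 by 0.93 ± 0.31, while the mean log2 ratio was -2.17 ± 0.39 for JUP over CTNNB1 and -1.99 ± 0.30 for KCNQ1 over KCNH2. Among metabolic genes, LDHB exceeded LDHA by 3.31 ± 0.49, PDK4 exceeded PDK2 by 3.17 ± 1.08, and the insulin-responsive glucose transporter gene SLC2A4 exceeded SLC2A1 by 2.34 ± 0.41. The ratio of NPPB over NPPA was -1.52 ± 0.71 and that of COL1A1 over COL3A1 was -2.30 ± 0.51. These 14 pairs had the same sign in 6 of 6 hearts and passed the exact two-sided sign-flip test (p = 0.03125, the smallest that 6 hearts can give, Benjamini-Hochberg adjusted p = 0.0402 over 18 pairs). The remaining 4 pairs did not pass: ACTC1 over ACTA1 at 0.42 ± 0.30 (adjusted p = 0.075 by the exact test), DSG2 over DSC2 at 0.25 ± 0.29, MYOM1 over MYOM2 at 0.02 ± 0.25 and HCN2 over HCN4 at -0.03 ± 0.52. Ratios of reads also follow transcript length: per kilobase of exon, ACTC1 over ACTA1 turned to -0.88 and MYOM1 over MYOM2 to -0.20, HCN2 over HCN4 turned to 1.05 and DSG2 over DSC2 was 1.27. Of these 4, all but MYOM1 over MYOM2 passed the exact sign-flip test per kilobase (adjusted p = 0.0331). The 14 passing pairs kept their sign per kilobase, but some moved in size. TNNI3 over TNNI1 moved to 10.6, CTNNA1 over CTNNA3 to 2.38, JUP over CTNNB1 to -1.09 and NPPB over NPPA to -0.83. Single hearts widened some SDs of the read ratios. PDK4 over PDK2 was 1.235 and DSG2 over DSC2 -0.31 in heart 2. JUP over CTNNB1 was -1.48 in heart 6 and CTNNA1 over CTNNA3 0.36 in heart 3.

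Gene lists fixed before the data were examined differed in how far they varied between hearts. Of the 27 lists with enough detected members, 13 varied more than 98% of random lists of the same size and like expression, and 0 varied less than the 2nd percentile. The adipocyte list was among the most variable: its score, the mean log2 level of its members relative to the 6-heart mean, spanned 7.96-fold between hearts and 3.23-fold without heart 3. PLIN1, which coats fat droplets, ranged from 1.65 to 58.7 RPM (from 8.64 RPM without heart 3), and the adipokine gene LEP and the fat droplet gene CIDEC had SDs of 2.63 on the log2 scale at means of 4.10 and 4.34 RPM, with 3 reads or fewer in heart 3 and SDs of 1.39 and 1.19 without it. LPL and PLIN4, which heart muscle also expresses, were less variable, with SDs of 0.62 and 0.40. The extracellular matrix list spanned 4.90-fold, and 3.26-fold without heart 4. COL1A1 ranged from 61.4 to 1078 RPM, COL3A1 from 420 to 3425 RPM, FN1 (fibronectin) from 611 to 2700 RPM and COMP from 0.807 to 68.4 RPM. Without heart 4 COL1A1 ended at 227 RPM, COL3A1 at 1031 RPM and FN1 at 1848 RPM, and without heart 2 COMP began at 4.27 RPM. The fibroblast list (99.3rd percentile) ranged less widely, with DCN (decorin) at 1372 ± 401 RPM.

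Genes of wall stress and of atrial muscle also varied. The natriuretic peptide genes NPPA and NPPB ranged from 44.8 to 2777 RPM and from 24.5 to 617 RPM (from 107 and 56.0 RPM without heart 5), while ANKRD1 ranged 2.06-fold and ACTA1 stood at 2798 ± 444 RPM. Most of the exon sequence of NPPA lies inside a gene on the other strand, so its level is uncertain, as are those of TTN, PLN and TGFB3 for the same reason. MYL7 stood at 440 ± 296 RPM and MYL4 ranged from 16.1 to 508 RPM; without heart 1 MYL7 stood at 338 ± 178 RPM and MYL4 ended at 103 RPM. In the sarcomere list (99.5th percentile), MYH6 ranged 7.69-fold, from 93.7 to 721 RPM (4.33-fold without heart 5), and TNNI3 3.14-fold. The nuclear genes of oxidative phosphorylation lay at the 99.9th percentile, with COX7A1 at 458 ± 190 RPM and COX6A2 at 156 ± 64.7 RPM. The other lists above the 98th percentile were smooth muscle and pericyte (MYH11 ranged 5.497-fold and TAGLN 4.67-fold), macrophage and monocyte (CD163 at 73.5 ± 28.4 RPM), neutrophil (S100A9 at 4.38 ± 3.97 RPM, and 2.92 ± 1.92 RPM without heart 1), Schwann cell (S100B at 4.96 ± 2.18 RPM), Wnt and Hippo (CYR61 ranged 8.24-fold) and long noncoding RNA. The endothelial list did not stand out (54.5th percentile), with VWF at 1087 ± 201.3 RPM and CDH5 at 112 ± 19.2 RPM. Neither did the lists of calcium handling (72.5th), ion channels (96.7th), fascia adherens and gap junction (9.10th), mast cell (25.6th), lymphocyte (85.6th), erythroid (93.0th), mesothelial (96.0th), fatty acid oxidation (87.6th), glycolysis and ketone use (93.0th), interferon response (93.4th), or immediate early and heat shock (93.1st). Several of the 13 calls ended when 1 heart was left out: fibroblast (78.6th percentile without heart 2), wall stress (95.9th without heart 2), Schwann cell (92.1st, 97.6th and 95.68th without hearts 2, 3 and 6), neutrophil (93.5th and 96.9th without hearts 1 and 5) and long noncoding RNA (94.8th without heart 4). The sarcomere call was also lost at CPM (97.02nd) and the Wnt and Hippo call without opposite-strand genes (88.4th).

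**Figure D2:**
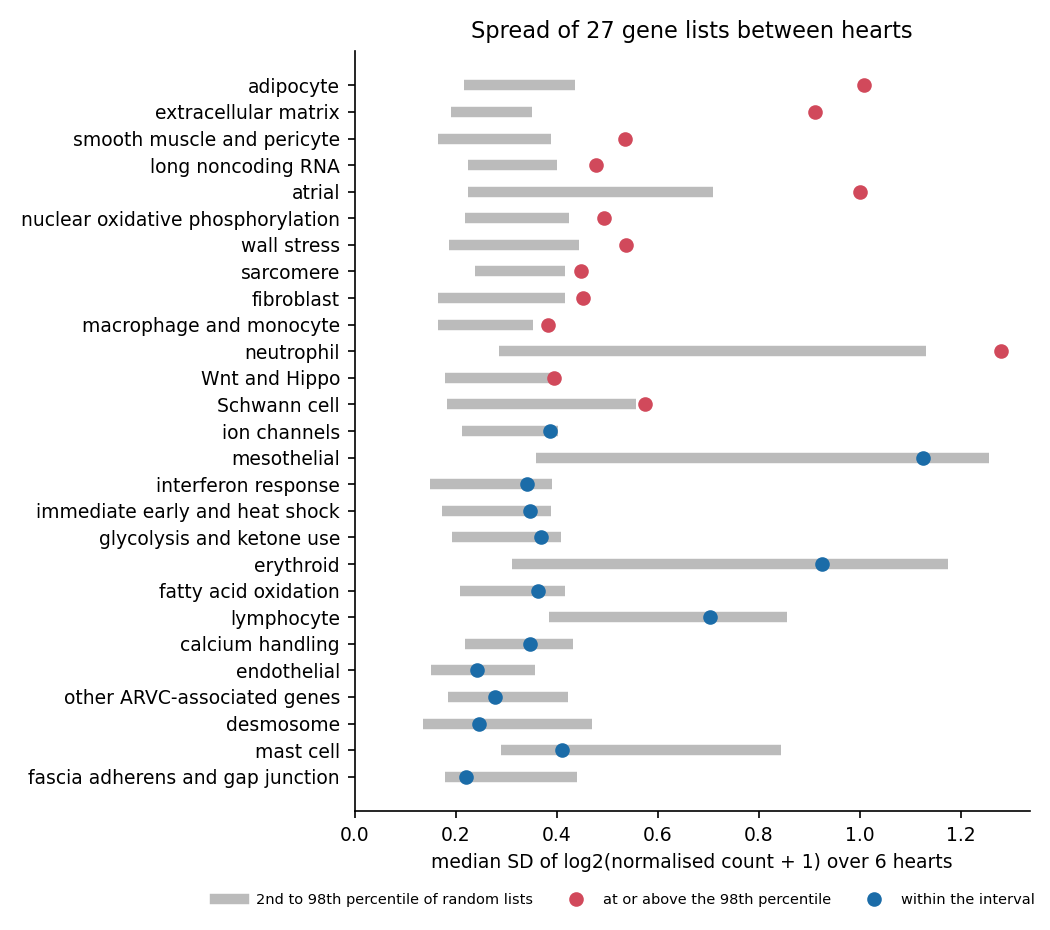
Median SD of log2(normalised count + 1) over 6 hearts for the members of 27 gene lists (points) against the range from the 2nd to the 98th percentile of 10000 random lists matched on size and expression (bars). The adipocyte and extracellular matrix lists lie farthest above their bars, and the desmosome and endothelial lists lie inside theirs.

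**Figure D3:**
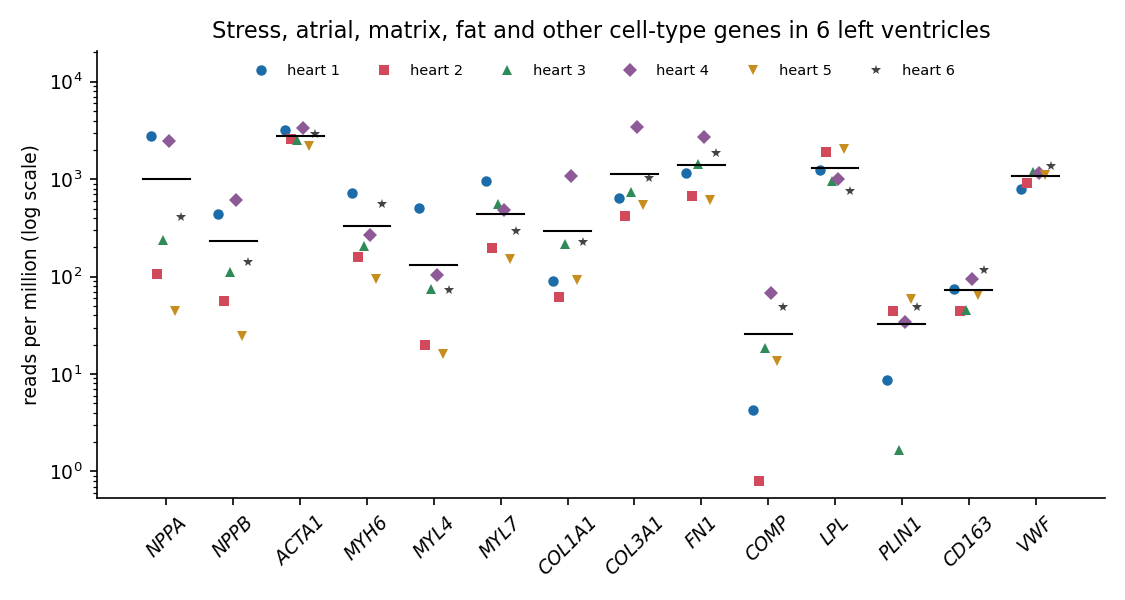
Levels of 14 genes of wall stress, atrial muscle, matrix, fat, macrophages and endothelium in RPM (log scale) in 6 left ventricles; each symbol is 1 heart and each bar the mean. NPPA ranged from 44.8 to 2777 RPM (from 107 RPM without heart 5) and COMP from 0.807 to 68.4 RPM (from 4.27 RPM without heart 2), while VWF ranged 1.59-fold.

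Members of 14 lists rose and fell together from heart to heart more than 98% of random lists did. The closest was oxidative phosphorylation, with a mean correlation between members of 0.936, followed by the extracellular matrix (0.771), glycolysis and ketone use (0.723), neutrophil (0.689), erythroid (0.660), fibroblast (0.655), macrophage and monocyte (0.643), adipocyte (0.552), Schwann cell (0.525), fatty acid oxidation (0.512), lymphocyte (0.461), Wnt and Hippo (0.447), atrial (0.417) and interferon response (0.380). The desmosome genes did not move together beyond chance (mean correlation 0.195, 77.3rd percentile), nor did the sarcomere (94.97th) or the wall stress list (55.9th). Neutrophil (87.3rd percentile without heart 1), atrial (97.2nd without heart 2), interferon response (68.5th without heart 2), lymphocyte (90.05th without heart 3) and erythroid (69.7th without heart 4) lost the call when 1 heart was left out, and fatty acid oxidation lost it without opposite-strand genes (97.5th). The 2 alpha-globin genes of the erythroid list, and FCGR3B of the neutrophil list, have near-identical copies whose reads could be split between them.

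Hearts with a higher extracellular matrix score had a lower sarcomere score. Of the 18 sarcomere genes, 14 had a negative r with the matrix score, and MYH6, ACTN2, LDB3 and NEXN had a positive one. Among 14 pairs of lists fixed before the data were examined, 4 were correlated across the 6 hearts by Pearson's r with an exact two-sided permutation test. The sarcomere and extracellular matrix scores gave r = -0.953 (exact permutation p = 0.00278, adjusted p = 0.0389 over 14 pairs), with Spearman's rho = -0.943 (p = 0.0167). The extracellular matrix and fibroblast scores gave r = 0.928 (exact permutation p = 0.0139, adjusted p = 0.0486) and rho = 0.943 (p = 0.0167). The sarcomere and fatty acid oxidation scores gave r = 0.928 (exact permutation p = 0.0139, adjusted p = 0.0486) and rho = 0.771 (p = 0.103). The fatty acid oxidation and oxidative phosphorylation scores gave r = 0.924 (exact permutation p = 0.00833, adjusted p = 0.0486) and rho = 0.886 (p = 0.0333). Without the 2 hearts farthest from the median of the first score these values were -0.922, 0.987, 0.599 and 0.680, so the last 2 relations rest in part on those hearts. Without heart 6, whose library stood apart, r was -0.976, 0.944, 0.893 and 0.888. The adipocyte score did not follow the extracellular matrix score (r = -0.308, exact permutation p = 0.560, rho = -0.371, p = 0.497) or the sarcomere score (r = 0.161, exact permutation p = 0.794, rho = 0.314, p = 0.564), and neither did the desmosome score follow the sarcomere score (r = 0.297, exact permutation p = 0.571, rho = 0.20, p = 0.714). The other 7 pairs had exact permutation p-values of 0.162 or more. By Spearman's rho 0 of the 14 pairs passed (smallest adjusted p = 0.117, exact permutation test), and after rescaling to CPM of each heart 0 passed (adjusted p = 0.0875 for each of the 4).

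**Figure D4:**
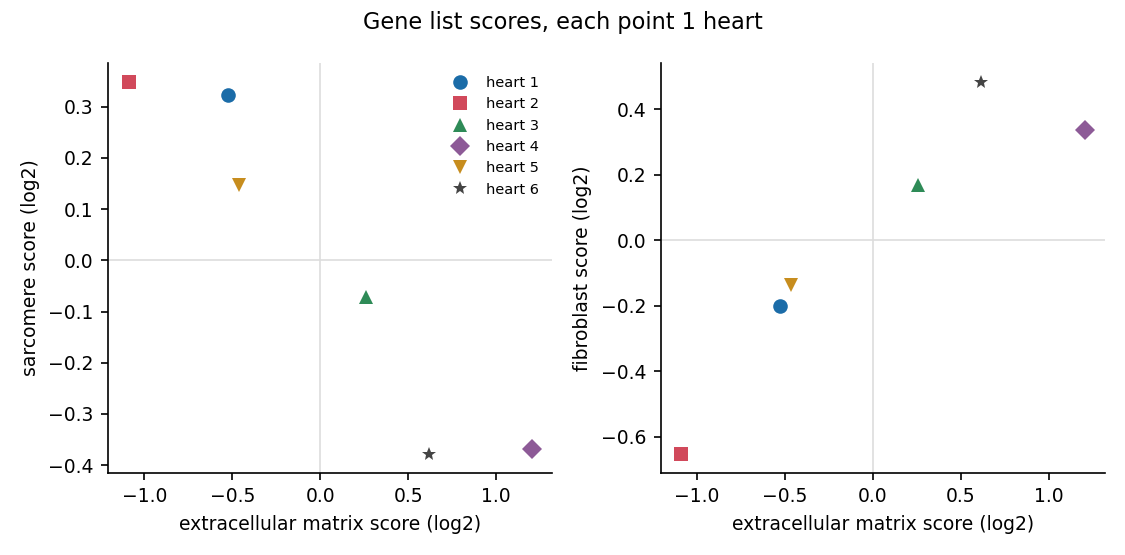
Scores of the sarcomere list (left) and of the fibroblast list (right) against the score of the extracellular matrix list, in log2 units relative to the 6-heart mean; each symbol is 1 heart. The sarcomere score falls (r = -0.953) and the fibroblast score rises (r = 0.928) with the matrix score.

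The series was set up around long noncoding RNAs, and 26 of the 28 listed were detected. After MALAT1, the highest were LINC00657 (830 ± 62.0 RPM, and 853 ± 33.0 RPM without heart 3), H19 (419 ± 170 RPM), NEAT1 (200.6 ± 97.01 RPM), KCNQ1OT1 (126 ± 50.5 RPM) and TUG1 (95.4 ± 27.7 RPM). DANCR, LINC00116, MIR22HG and DNM3OS stood between 31.1 and 41.9 RPM. The steadiest of these was LINC00657, with a range of 1.21-fold between hearts, and the most variable listed were HOTAIRM1 (0.641 ± 0.594 RPM, and 0.421 ± 0.284 RPM without heart 5) and TTN-AS1 (11.7 ± 11.0 RPM). Heart 6 alone made TTN-AS1 variable, with 7.25 ± 2.26 RPM in hearts 1 to 5. TTN-AS1, KCNQ1OT1 and DNM3OS overlap genes on the other strand, and the use of strand in counting is not given in the sources used here, so their levels are uncertain. Symbols classed as long noncoding by RefSeq held 1.08% of all reads, with 906 of 1849 detected.

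No library was a copy of another: read counts of each pair differed by 55.9 to 326 times the sampling variance. The library of heart 6 stood apart, with Spearman correlations of 0.959 to 0.974 across genes with the other libraries, against 0.971 to 0.990 among hearts 1 to 5. Correlations across genes describe the libraries, since genes are not independent replicates. The first principal component held 50.8% of the variance and separated heart 6 from the rest. All 20 of the most variable genes by the fixed rule, led by CDR1, LOC148696, MIRLET7DHG and MIF, were most extreme in heart 6, and without heart 6 only 1 of them was among the 20 most variable. The median SD per gene was 0.33 on the log2 scale with all hearts and 0.29 without heart 6. By the fixed rule the smallest SDs for their level were those of TRAIP (1.12 ± 0.0637 RPM) and POC1A (0.928 ± 0.0862 RPM). Both genes had few reads, with mean normalised counts of 66.1 and 54.9. Counting noise is large at such counts, so their small SDs may be chance and do not show steady expression.

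**Figure D5:**
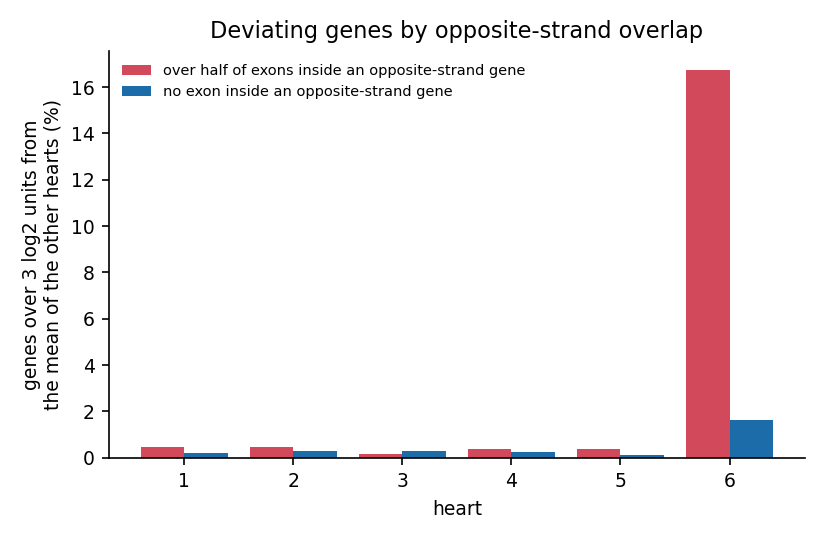
Share of genes lying more than 3 log2 units from the mean of the other 5 hearts, in percent, for each heart, among genes with over 50% of their exons inside a detected opposite-strand gene and genes with none. Heart 6 reaches 16.7% and 1.63%, and no other heart exceeds 0.467%.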

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

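The tests of the strand handling of heart 6 on the matrix relation, of the share of muscle cells and of poly(A) selection were chosen after the results they measure had been seen; the tests of strand, depth, gene models and biology given here were written before their results were seen, although the pattern itself was found in these data. Of 211 results tested for 1 heart lying far from the other 5, 26 did, against about 10.6 expected by chance (1 in 20); the share of the range taken by the gap is given for each. Outside the most and least variable genes, 6 of 181 stood out, a share below 1 in 20. Many of these results share genes, and all use the same hearts. The counts are therefore not of independent results, and their difference from chance was not tested. The 6 that stood out were reads per heart (0.752), the erythroid score (0.629), the log2 ratio of DSG2 over DSC2 (0.677), and the log2 levels of DSP (0.654), HBA2 (0.690) and PDK4 (0.645). POC1A, picked for its small SD for its level, did too (0.687).

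The other 19 are among the 20 most variable genes and were chosen for that, so their number is no evidence in itself: CDR1 (0.841), LOC148696 (0.949), MIRLET7DHG (0.944), MIF (1.000), ANKRD36BP1 (0.928), BEND3P3 (0.758), CELF2-AS2 (0.858), TMEM14E (0.863), KCNJ13 (0.844), CD160 (0.881), THRIL (0.927), RBM5-AS1 (0.946), HYI (1.000), TREH (0.708), LOC349160 (0.843), CACNA1C-AS4 (0.843), C1orf192 (0.878), RBM12B-AS1 (0.907) and MYH4 (0.650). In each, heart 6 was the one apart.

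The library of heart 6 had the fewest genes with a read (20285, against 20474 to 22119 in the others) and was the least like the others. Its greater depth does not account for the lower similarity: thinned to the 35911701 reads of the shallowest library, its mean correlation with the others was 0.9655, below the lowest of the other 5 (0.975). A candidate explanation is that strand was used for heart 6 alone, in the library or in the counting: 16.7% of genes with over 50% of their exons inside an opposite-strand gene lay more than 3 log2 units from the other hearts, 10.27 times the share among genes with no such overlap. Other gene models for heart 6 stay open: of 76 genes read on one side only, 55.26% (95% Wilson interval 44.1 to 65.9%) lay over 50% inside an opposite-strand gene, against 7.90% of all genes. The interval treats genes as independent draws, which they are not, so it describes these libraries only. Biology of heart 6 also stays open in part, since 65.19% of the correlation gap was left without any overlapping gene.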

How the results depend on the processing

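Tests without opposite-strand genes, by edgeR dispersion, and of similarity and detection under other settings were added after seeing the data. The 14 ratio calls held at pseudocounts of 0.5 and 5; per kilobase 17 pairs passed, and ACTC1 over ACTA1 (-0.88), MYOM1 over MYOM2 (-0.20) and HCN2 over HCN4 (1.05) changed sign because of exon lengths. Leaving out each heart, 14 to 15 pairs had one sign in all hearts left. The count could not fall below 14, since one sign in 6 hearts holds in any 5 of them. With 5 hearts the smallest sign-flip p is 0.0625, so no call is possible. Without opposite-strand genes fewer pairs were tested, and 9 of the 14 were left to pass. Their ratios were unchanged by this setting, so all 9 had to keep one sign. Lists called more variable numbered 10 to 15 and coherent 12 to 15 under all settings; 6 of 13 and 8 of 14 kept the call under every setting. Left-out hearts also added calls, such as ion channels (99.5th percentile without heart 6).

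The correlation calls were the least stable. The count fell from 4 to 0 at CPM, by Spearman correlation and with the median score, and to 1 without opposite-strand genes (sarcomere with extracellular matrix); leaving out each heart gave 0 to 0, where 5 hearts allow no p below 0.00833. Ranges over the same settings include rho at the Spearman setting. The correlation of sarcomere with extracellular matrix lay between -0.976 and -0.918. That of sarcomere with fatty acid oxidation lay between 0.771, which is rho, and 0.983. That of extracellular matrix with macrophage lay between -0.686 and 0.551. At CPM, which shifted the median gene by up to 0.13 (log2) in a heart, sarcomere with desmosome (-0.29), extracellular matrix with macrophage (0.12) and macrophage with lymphocyte (0.0761) changed sign, the last also under TMM (0.00259) and by rank (0.0286); none was past the threshold.

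The most variable genes depended on the measure: 13 of 20 were shared at pseudocount 5 and 8 by edgeR dispersion. By the median absolute deviation, which ignores 1 outlying heart, 0 were shared. Leaving out hearts gave 1 to 19. Without opposite-strand genes 4 were shared, and 1 without heart 6 as well. Both of these settings left out the 11 of the 20 that overlap an opposite-strand gene. They also left out those not matched to GENCODE 29, since 15 of the 20 were matched. The most they could share was therefore 4, so these counts say little about the measure. The lowest correlation between hearts was 0.948 at a minimum of 50, and 0.959 to 0.971 leaving out each heart. The median SD was 0.46 with no minimum, 0.29 at a minimum of 50, and 0.29 to 0.34 leaving out each heart. The causes of these shifts were not tested. No paired analysis was possible because no sample is paired with another in the labels.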

Other observations

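The relations of the matrix score to all other lists, and the ranking of variable genes without heart 6, were computed after seeing the data, as were the tests of the share of muscle cells, of the strand handling of heart 6, of poly(A) selection and of neighbouring genes. Across the 6 hearts the extracellular matrix score fell with calcium handling (r = -0.965, exact permutation p = 0.00278, adjusted p = 0.0241 over 26 lists; rho = -0.943, p = 0.0167), glycolysis and ketone use (r = -0.936, exact permutation p = 0.00694, adjusted p = 0.0361; rho = -1, p = 0.00278) and oxidative phosphorylation (r = -0.941, exact permutation p = 0.0111, adjusted p = 0.0482; rho = -0.886, p = 0.0333). It rose with the Wnt and Hippo list (r = 0.949, exact permutation p = 0.00556, adjusted p = 0.0361; rho = 0.943, p = 0.0167), which includes the matrix-associated CYR61, and with the long noncoding RNA list (r = 0.954, exact permutation p = 0.00278, adjusted p = 0.0241; rho = 1, p = 0.00278). Without the 2 hearts farthest from the median these were -0.868, -0.914, -0.985, 0.983 and 0.853, and with the sarcomere list 6 of 26 passed by Pearson's r and 2 by Spearman's rho. The fibroblast list, which passed over 14 pairs, missed the threshold in this wider family (r = 0.928, exact permutation p = 0.0139, adjusted p = 0.0516). Members of the long noncoding RNA list did not move together (mean correlation 0.0265, 84.0th percentile), and its score spanned only 1.41-fold. Its relation to the matrix score is therefore one of the list mean and need not hold for each member.

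Genes were ranked without heart 6 and without opposite-strand or unmatched genes. The most variable of these 10574 genes included 4 of the adipocyte list, CIDEC, LEP, SCD and PLIN1, together with COMP, MYL4 and NPPB. SCD, a lipid desaturase gene, stood at 128 ± 222 RPM, and at 38.4 ± 33.0 RPM without heart 2. Genes of that ranking outside the lists included TF (transferrin, 10.5 ± 15.9 RPM, or 4.07 ± 3.17 RPM without heart 2), ACTG2 (a smooth muscle actin close in sequence to ACTA2 and so uncertain, 8.52 ± 10.7 RPM, or 4.31 ± 3.16 RPM without heart 4) and DLK1 (4.92 ± 5.74 RPM, or 3.07 ± 3.96 RPM without heart 2).

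The sarcomere and oxidative phosphorylation scores moved against the extracellular matrix score. Transcript length and GC content as whole causes are argued against by r = -0.9544 and -0.9402 after their trends were removed from each heart, and the strand handling of heart 6 by r = -0.9762 without that heart. The endothelial score did not rise with the matrix score: its slope was -0.0813 (-0.17 to -0.05 leaving out each heart). The slopes of the other cell types went both ways: fibroblast 0.46, smooth muscle 0.43, lymphocyte 0.35, Schwann cell 0.10, macrophage -0.04, mast cell -0.11 and adipocyte -0.39. The slope test and its bound were chosen after the scores had been seen, so they cannot decide whether a lower share of cardiomyocytes alone was the cause. A change in the cells whose scores rose, and the place where each sample was taken, stay open and untested, since no label separates them.

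RPPH1 and RMRP, which have no poly(A) tail, together took 2.94 ± 0.77% of reads. Reads of neighbouring genes are argued against, since each was at least 520.1 times as abundant as PARP2 or CCDC107 in every heart. Libraries made without poly(A) selection stay open: 59 of 73 histone symbols, picked by name alone as replication-dependent, were detected. The median histone gene lay at percentile 24.1 of detected genes, between the bounds set for either answer. SCARNA2, another small RNA without a tail, chosen after its values were seen, stood at 1326 ± 243 RPM. No biological explanation of these levels was tested.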
